A study of Mus musculus with 16 samples.

How the data were processed

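Total RNA from the livers of 16 mice was labelled with Cy3 after priming with a mixture of random and oligo-dT primers, per the labels, and each sample was hybridised to 1 of 16 subarrays on 2 slides. Each scanner file holds spot intensity values that, per the file headers, Agilent Feature Extraction made by subtracting background and removing spatial trends within the array, without scaling between arrays. The labels name Agilent Feature Extraction 11 and Partek. The deposited value table holds log2 values that the authors had quantile normalised across the 16 arrays, since all 16 columns had the same median, 4.36, and differed by at most 0.0063 from quantile-normalised log2 values recomputed from the scanner files.

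For 6 of 16 samples, the slide in the label was not that of the scanner file listed for the sample. Each column of the value table was therefore correlated with each scanner file, after removing each probe's mean. All 6 columns matched best the file at the slide and position in the label (r from 0.885 to 0.996), against -0.3 to 0.168 for the listed file, and the other 10 matched their listed file (r from 0.909 to 0.996). By a rule set before the data were examined, the value table with its columns by sample was then used for all values here, and groups were taken from the labels. By the labels, the first slide held 3 H/A, 2 WT, 2 Flox and 1 Del array, and the second 1 H/A, 2 WT, 2 Flox and 3 Del arrays. By the names of the listed files, all H/A arrays lay on the first slide and all Del arrays on the second. A block by file name therefore overlaps with genotype.

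Each array had 62976 spots, 1439 of them controls, and 60037 distinct probes, of which 36264 could be given a gene symbol through the transcript identifiers of the GRCm38.p6 reference. No coordinates are given, since the array was designed on another assembly. The 37819 probes that the scanner software marked as well above background on at least 4 of 16 arrays, whatever their group, were kept. The probe with the highest mean signal stood for each gene, which left 31484 genes. A gene marked on 0 arrays of 1 group was given as an "at least" fold against the dimmest marked signal of each array, or the gene's own signal where that was higher.

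All genes were fitted in 1 linear model of the 16 arrays with limma 3.58.1 in R 4.3.3, with moderated tests, for 5 comparisons: H/A with WT, Del with WT, Flox with WT, Del with Flox and H/A with Del. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and "rose" and "fell" are used of called genes only. Intervals are 95% intervals of single genes, unadjusted. The text names genes from the 12 largest rises and 12 largest falls of each comparison, leaving out names that are only identifiers, from the ceramide synthases, and from the 4 members with the smallest p of each list. A few further list members and the small nucleolar RNA genes were chosen after their values were seen.

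Before the data were examined, 22 gene lists and 10 lists of cell type markers were fixed. The gene lists covered sphingolipid metabolism, fatty acid elongation, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation and PPAR alpha targets, lipid uptake and lipid droplets, lipoproteins and LXR targets, mitosis, DNA replication, p53 targets, fetal liver and hepatocellular carcinoma markers, unfolded protein response, NRF2 targets, acute phase and cytokines, bile acid synthesis and transport, xenobiotic metabolism, glucose metabolism and insulin signalling, male-biased and female-biased liver genes, circadian clock, pericentral genes and periportal genes. The cell types were hepatocyte, cholangiocyte, Kupffer cell and macrophage, lymphocyte, neutrophil, stellate cell and fibroblast, sinusoidal endothelial cell, erythroid cell, pancreatic acinar cell and adipocyte. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison, and beside it with an estimated correlation and with fry. Camera compares a list with all other genes, and fry asks whether a list's own genes move one way.

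The procedure was tested on simulated data in which 200 of 31484 genes were changed in each of 5 runs. It recovered 6% of genes changed by 0.5 on the log2 scale, 65.2% at 1, 96% at 2 and 99.2% at 4. Of its calls 6.7% were false, it made 0 calls in an unchanged comparison, and it found a shifted list in 5 of 5 runs. The simulated values were drawn independently for each gene and array, without correlation between genes or slide effects. So these rates do not test the preset correlation of camera and may not hold for the measured data. There, other splits of the H/A and WT arrays called a median of 8 lists.

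The alternatives tried were the scanner files as listed and as paired by label (scaled by their 75th percentile), quantile normalisation recomputed, no scaling, a normexp background correction with an offset of 50, no filter and a filter on all 16 arrays, the mean of a gene's probes, other variance models, array weights, and the slide by label or by file name as a block. Fits within each slide, of the compared groups alone, without the 6 samples above, without each sample in turn, and with a required change of at least 1 on the log2 scale were also run. Fits restricted to named genes or without small nucleolar RNA genes were added after the data were seen. For each comparison all 35 splits of the 8 arrays were refitted. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures. Controls and probes without signal were left out, and no column of per-sample values other than those named was used here.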

Results

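Liver RNA from 16 male mice, 6 weeks old, was measured on 1-colour expression arrays, with 1 array per mouse. CerS2 (ceramide synthase 2) is the enzyme that joins very long acyl chains to sphingoid bases to make ceramides. The labels name 4 genotypes of its gene with 4 mice each. WT is wild type, H/A is read here as a line with histidine replaced by alanine in the catalytic site, and Del and Flox are further engineered lines. The labels also call the Del condition delHox and the Flox condition delneo, without saying what these alleles contain. All mice carried a mixed C57BL/6 and SV129 background. On average 58.1% ± 3.2 (SD, n = 16) of the spots of an array were well above background, with a range of 51.6% to 65.2%, and no array had a saturated spot. The group means were 57.6% for WT, 58.8% for H/A, 56.5% for Del and 59.2% for Flox. Before scaling, the 75th percentile of the spot signal was 89.7 to 98.8 in WT and 109.3 to 173.1 in H/A. It was 91.2 to 114.8 in Del and 86.0 to 111.6 in Flox, so the H/A arrays were brighter than the WT arrays. The number of arrays limits the precision of every value below.

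After filtering, 31484 genes were tested, of which 17666 carried a gene symbol. Within a genotype, pairs of arrays correlated across genes with r from 0.964 to 0.985, where genes are not independent replicates. The first principal component held 43% of the variance and set the WT and Flox arrays (11 to 65.1) apart from the H/A and Del arrays (-92.6 to -19). WT replicate 2, at 11, lay nearest to the H/A and Del arrays. The second component held 8.7%.

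**Figure D1:**
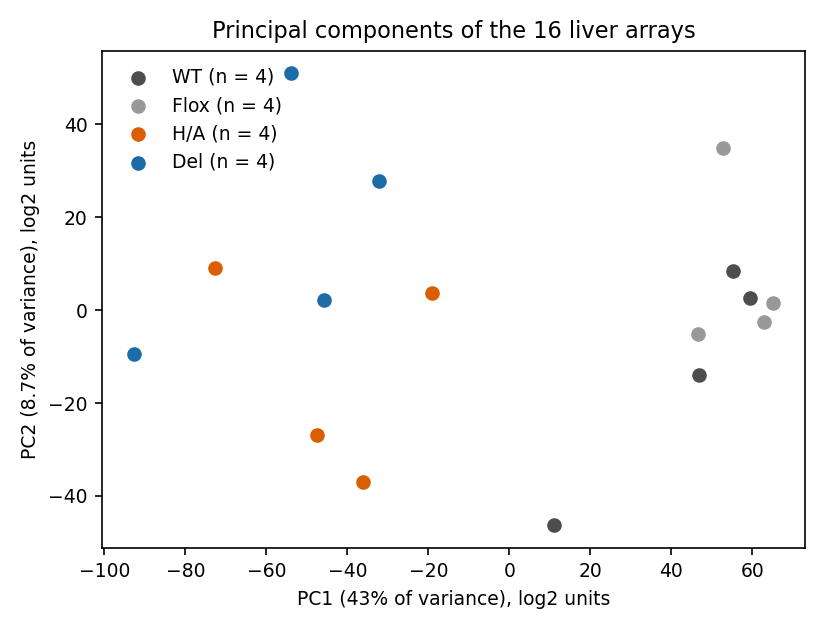
Each point is 1 liver array, placed by its scores on the first (43% of variance) and second (8.7%) principal components, in log2 units, and coloured by genotype (4 arrays each). The WT and Flox arrays lie at 11 or above on the first component and the H/A and Del arrays at -19 or below.

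Cers2 itself could not be followed, because no probe could be paired with its name, and so the engineered gene was not analysed here and the genotype labels could not be checked against it. Among the other ceramide synthases, Cers1, Cers4, Cers5 and Cers6 were well above background on all 16 arrays and Cers3 on 0. Cers5 rose in H/A by 0.92 on the log2 scale (95% interval 0.43 to 1.42, adjusted p = 0.0224) and in Del by 0.77 (0.28 to 1.27, adjusted p = 0.0397), both against WT with 4 mice per group, and in both lines every mutant array lay above every WT array. Cers6 differed by 0.76 in H/A (adjusted p = 0.0655) and by 0.61 in Del (adjusted p = 0.113) and did not pass. Cers4 differed from WT by -0.41 in H/A (adjusted p = 0.115) and by -0.43 in Del (adjusted p = 0.0987), and Cers1 by -0.22 in both (adjusted p = 0.237 and 0.221), and neither passed. In Del against Flox all 4 passed, with rises of Cers6 by 0.92 and Cers5 by 0.67 and falls of Cers4 by -0.52 and Cers1 by -0.45 (adjusted p from 0.0156 to 0.0386). In Flox against WT 0 of 4 were called with limma, with differences from -0.31 to 0.23 and intervals reaching from -0.85 to 0.60. Without scaling between arrays, Cers1 and Cers4 in H/A against WT turned to 0.31 and 0.14. Over the 5 comparisons 6 of 20 values passed, which became 10 without WT replicate 2, 1 without Del replicate 3, and 3 without either Del replicate 1 or Flox replicate 3. The Cers5 call was lost in H/A against WT without H/A replicate 3 (0.74) or WT replicate 4 (0.72). In Del against WT it was lost without WT replicate 4 (0.57), Del replicates 1, 3 or 4 (0.79, 0.61 and 0.82), or Flox replicate 3 (0.77). Both Cers5 calls were also lost with normexp background correction (0.17 in H/A and 0.23 in Del) and in fits of the 2 groups alone (0.92 and 0.77). That in Del was lost too without scaling (0.78), without a filter or with an unmoderated model (0.77 in both), and with the slide of the file name as a block (1.01). In Del against Flox the calls of Cers1 (-0.38) and Cers6 (0.86) were lost without Del replicate 3. That of Cers4 was lost without Del replicates 1 or 3 (-0.49 and -0.40) or Flox replicates 3 or 4 (-0.50 and -0.43). That of Cers5 was lost without Del replicates 1, 3 or 4 (0.69, 0.50 and 0.72) or Flox replicates 1, 3 or 4 (0.62, 0.64 and 0.62). No scaling ended the calls of Cers1, Cers4 and Cers5 there (-0.31, -0.35 and 0.67) and normexp those of Cers4 and Cers5 (-0.35 and 0.22). Label-paired files (-0.43) or the 2 groups alone (-0.52) also ended that of Cers4, and no filter, an unmoderated model (0.67 in both) or array weights (0.57) that of Cers5. Without WT replicate 2, Cers6 passed against WT in H/A (0.92) and Del (0.77), as did Cers4 (-0.55 and -0.58). Cers6 in H/A also passed without Flox replicate 1 (0.76).

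The comparison of H/A with WT asks what the H/A allele does to liver transcripts. In H/A livers 30 of 45 mitosis genes, 22 of 34 genes of DNA replication and 15 of 20 targets of NRF2 rose. NRF2 is the transcription factor of the oxidative stress response. Of 18 male-biased genes, which are expressed more highly in male than in female mouse liver, 10 fell. Camera called these 4 lists at its preset correlation but not with an estimated correlation (adjusted p from 0.116 to 0.312). Atf3, a stress-induced transcription factor, was at least 13.5-fold higher in H/A (7.22 ± 0.60 against 2.40 ± 0.88 on the log2 scale, SD, n = 4; adjusted p = 3.61e-05). Ly6d rose by 4.37 on the log2 scale (95% interval 3.61 to 5.12), the glutathione transferases Gsta1 and Gsta2 rose by 4.21 and 4.02, and Osbpl3, which encodes an oxysterol-binding protein relative, was at least 6.18-fold higher. The interferon-induced chemokine gene Cxcl10 was at least 6.52-fold higher, and Ubd, another interferon-induced gene, rose by 4.14 (adjusted p = 0.00116). The largest falls were those of Serpina4-ps1 (-8.00, interval -10.68 to -5.31), the male-specific steroid dehydrogenase gene Hsd3b5 (-6.64, -8.64 to -4.65) and the fatty acid elongase gene Elovl3 (-5.69, -8.45 to -2.93). Each of these genes belongs to the male-biased list, so their falls are part of that list's result. Slco1a1, an organic anion transporter gene, fell by 4.56, and the major urinary protein genes Mup3 and Mup14, whose probes can share targets, fell by 5.46 and fell by 4.08. Mup14 stayed called only without H/A replicates 1 or 4, WT replicate 2, Del replicate 3 or Flox replicate 1, and was at -2.46 without H/A replicate 3. Its call was also lost with the slide as a block by label (-3.83) or by file name (-4.19), with no filter, with trend and robust moderation, with an unmoderated model and in the 2 groups alone (-4.08 in each). Slco1a1 was not called in the 2 groups alone (-4.56). Without H/A replicate 3 Slco1a1 was at -3.15 and Mup3 at -4.25, and over all 16 left-out arrays they ranged to -5.25 and -6.26.

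Of 45 mitosis genes tested, 30 rose and 0 fell in H/A against WT (33 and 3 adjusted over the list alone), with a median change of 1.77. The kinase gene Aurkb was at least 2.07-fold higher, Ccnb2, a mitotic cyclin gene, rose by 3.18 and Cdca3 by 2.87. The list shifted relative to other genes with camera (adjusted p = 2.35e-16), but not with an estimated correlation (adjusted p = 0.148). Of 34 DNA replication genes, 22 rose and 0 fell (23 and 1 adjusted over the list alone), among them Ccnd1, the gene of cyclin D1, by 2.00, Rrm1 by 1.29 and Chaf1a by 1.69, with a list median of 1.09 (adjusted p = 4.36e-14; 0.116 with an estimated correlation). Of 20 NRF2 targets, 15 rose and 0 fell (15 and 0 adjusted over the list alone), including Ephx1 by 1.00 and Ugdh by 1.82. The list median was 1.34 (adjusted p = 3.36e-12; adjusted p = 0.148 with an estimated correlation). Markers of fetal liver and hepatocellular carcinoma had a median of 2.17, and 10 of 19 rose and 1 fell (11 and 2 adjusted over the list alone), with Golm1 up by 3.53, Lgals1 by 2.30 and Anxa2 by 2.89 (adjusted p = 3.94e-07; adjusted p = 0.117 with an estimated correlation).

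Markers of Kupffer cells and macrophages rose beside these groups in H/A. Of 17 tested, 12 rose and 0 fell (12 and 1 adjusted over the list alone), with Cd14 up by 2.88, Adgre1, the gene of the macrophage protein F4/80, by 1.70, Mpeg1 by 1.57 and Cd5l by 1.32. Their median was 1.25 (adjusted p = 3.94e-07; adjusted p = 0.148 with an estimated correlation). Male-biased liver genes fell, 10 of 18 with 0 rising (15 and 0 adjusted over the list alone), at a median of -2.20 (adjusted p = 4.69e-08; adjusted p = 0.312 with an estimated correlation). Female-biased liver genes went both ways, with 8 of 23 rising and 3 falling (13 and 4 adjusted over the list alone) and a median of 1.11 (adjusted p = 0.000121; adjusted p = 0.343 with an estimated correlation). Cyp3a41a rose by 2.08 and Cyp3a44 by 2.03, whose probes can share targets, and Rtn4 rose by 1.80 (0.71 to 2.15 over its 3 probes).

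In the sphingolipid pathway, 9 of 32 genes rose and 2 fell in H/A (13 and 3 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.00601; adjusted p = 0.166 with an estimated correlation). The rises included Sptlc2, a subunit of the serine palmitoyltransferase that starts the pathway, by 1.38, the ketosphinganine reductase gene Kdsr by 1.00, the ceramide transport gene Cert1 by 0.87 and the ceramide kinase gene Cerk by 0.79. Of 21 p53 targets 4 rose and 0 fell (6 and 0 adjusted over the list alone), including Phlda3 by 2.02, Tnfrsf10b by 2.59 (0.23 and not called with normexp) and Bax, a call lost without H/A replicate 2 (0.68) or WT replicate 3 (0.63), by 0.73 (adjusted p = 0.000833; adjusted p = 0.166 with an estimated correlation). Of 27 genes of fatty acid oxidation and PPAR alpha targets 5 rose and 0 fell (6 and 1 adjusted over the list alone), including Acadm by 0.90 and Cpt1a by 0.87 (adjusted p = 0.00576; adjusted p = 0.536 with an estimated correlation and 0.0953 with fry). Without H/A replicate 1 this list was not called (adjusted p = 0.0855), and without H/A replicates 2 or 3 or WT replicate 1 Cpt1a was not (0.81, 0.78 and 0.79). The other 22 lists were not called with camera in H/A against WT, with adjusted p from 0.116 to 0.959, while fry called 2 of them, lipid uptake and lipid droplets (adjusted p = 0.00421) and bile acid synthesis and transport (0.0334). They were fatty acid elongation, fatty acid and triglyceride synthesis, cholesterol synthesis, lipid uptake and lipid droplets, lipoproteins and LXR targets, unfolded protein response, acute phase and cytokines, bile acid synthesis and transport, xenobiotic metabolism, glucose metabolism and insulin signalling, circadian clock, pericentral genes, periportal genes, hepatocyte, cholangiocyte, lymphocyte, neutrophil, stellate cell and fibroblast, sinusoidal endothelial cell, erythroid cell, pancreatic acinar cell and adipocyte.

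In all, 3166 genes were called between H/A and WT, 2230 higher and 936 lower in H/A, of which 2119 carried a symbol. A fit with the slide as a block called 2745 genes. There were 14 calls within the slide holding 3 H/A and 2 WT arrays, and 626 within the slide holding 1 H/A and 2 WT arrays. Where a slide held a single array of a group, here and below, the spread came from the other groups, so its counts and p values say little about that group. Between these slides, in that order, the list medians were 1.22 and 2.89 for mitosis, 0.68 and 1.32 for DNA replication, 1.23 and 1.38 for NRF2 targets, 1.88 and 2.14 for fetal liver markers and 1.13 and 1.20 for macrophage markers. Male-biased genes gave -2.70 and -0.90, female-biased genes 1.54 and 0.17 (adjusted p = 0.174 in the latter), sphingolipid genes 0.19 and 0.26 (adjusted p = 0.0699 in the latter), p53 targets 0.25 and 0.67, and fatty acid oxidation genes 0.39 and 0.00 (adjusted p = 0.903 in the latter). With the slide as a block these lists, in the same order, had medians of 1.70, 1.09, 1.28, 2.02, 1.21, -2.10, 1.14, 0.22, 0.36 and 0.17. The count rested on single arrays, ranging from 1450 without WT replicate 4 to 8021 without WT replicate 2, and falling to 1593, 1542, 2101, 1986 and 1619 without H/A replicates 2, 3 and 4 and WT replicates 1 and 3. Without scaling between arrays, which moved the median of all genes from -0.09 to 0.37, 98.7% of 9543 calls were higher in H/A, against 70.4% here, and with another background correction 38% of 10764 were.

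**Figure D2:**
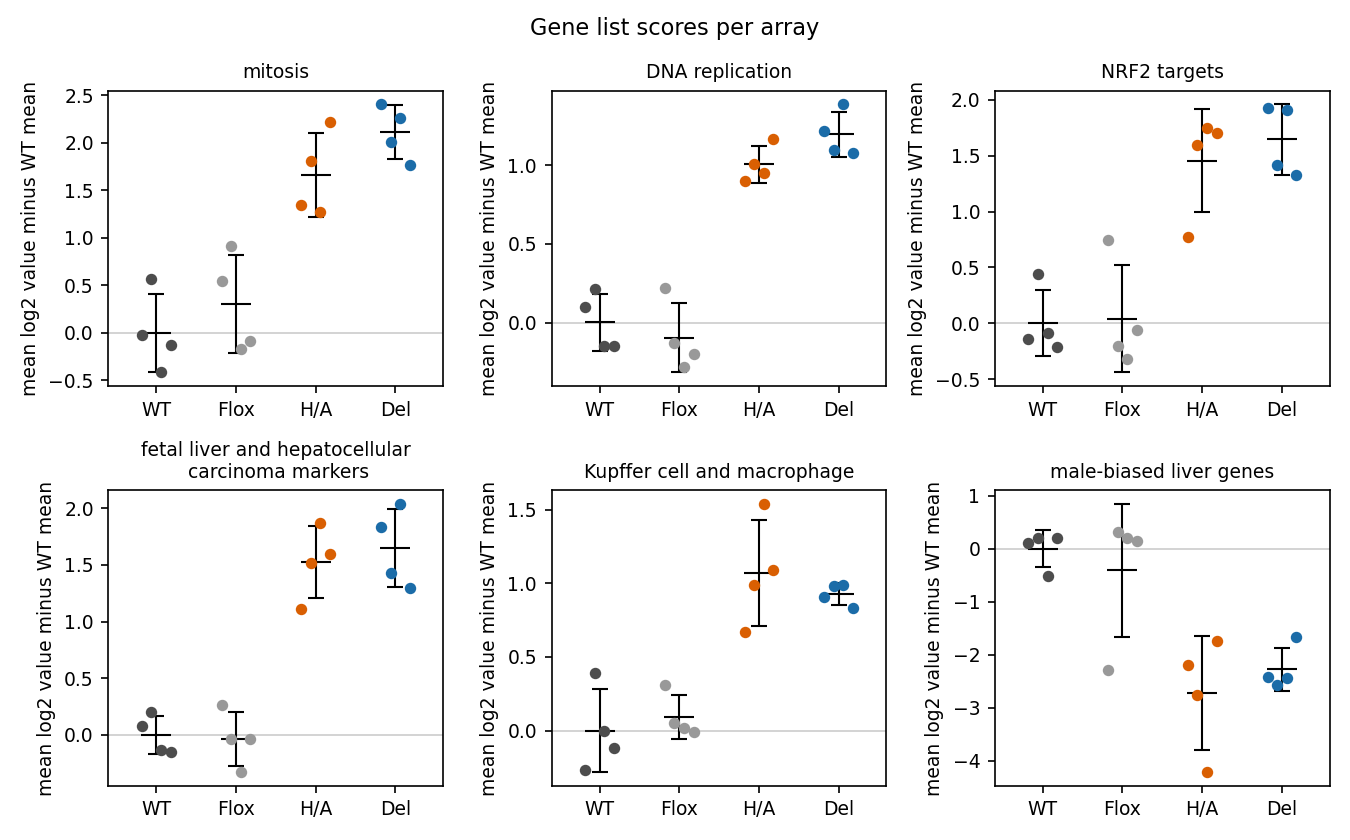
Points are arrays (4 per genotype), bars the mean ± SD, and the vertical axis the mean log2 value of the list's genes minus the WT mean. All 8 H/A and Del arrays lay above the 8 WT and Flox arrays for mitosis, DNA replication, NRF2 targets, fetal liver markers and macrophage markers, while Flox replicate 1 lay at -2.29 for male-biased genes, among the H/A and Del arrays.

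The comparison of Del with WT asks the same of the Del allele. In Del livers 33 of 45 mitosis genes, 22 of 34 replication genes and 17 of 20 NRF2 targets rose and 11 of 18 male-biased genes fell, in lists that were not called with an estimated correlation (adjusted p from 0.0693 to 0.447). Small nucleolar RNA genes made up 6 of the 12 largest falls. Atf3 was at least 17.1-fold higher in Del (7.57 ± 0.32 against 2.40 ± 0.88 on the log2 scale, SD, n = 4; adjusted p = 1.16e-05), Ly6d rose by 5.01 (95% interval 4.25 to 5.76), Gsta1 by 4.74 and Gsta2 by 4.33. Ccnb1, the gene of cyclin B1, was at least 6.97-fold higher, and Abcb1b, a drug efflux pump gene, at least 4.55-fold higher, though Del replicate 2 lay at 1.83 on the log2 scale against 6.52 to 7.16 on the other Del arrays. Without that array the log2 change of Abcb1b was 5.70 instead of 4.43. Hsd3b5 fell by 6.99 (interval -8.99 to -5.00), Serpina4-ps1 fell by 6.80 and Elovl3 fell by 5.08, the last not called without Del replicate 3 (-4.43). Snora30 fell by 4.67 (-6.23 to -3.11), Snord69 fell by 4.40, and Snora21 was at least 16.2-fold lower.

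Of the 45 mitosis genes 33 rose and 0 fell in Del (34 and 1 adjusted over the list alone), with Mki67, the gene of the proliferation marker Ki-67, up by 2.35 and Aurkb at least 2.98-fold higher (median 2.38, adjusted p = 1.41e-22; adjusted p = 0.0911 with an estimated correlation). Of 34 DNA replication genes 22 rose and 1 fell (22 and 1 adjusted over the list alone), with Mcm2, a subunit of the replicative helicase, up by 2.84 and Uhrf1 by 3.17 (median 1.23, adjusted p = 2.38e-15; adjusted p = 0.0693 with an estimated correlation). NRF2 targets rose in 17 of 20 cases and fell in 0 (17 and 1 adjusted over the list alone), with Srxn1 up by 2.90 and Ugdh by 2.10 (median 1.37, adjusted p = 1.82e-13; adjusted p = 0.0911 with an estimated correlation). Among p53 targets 10 of 21 rose and 0 fell (12 and 0 adjusted over the list alone), with Phlda3 up by 2.63 and Tnfrsf10b by 3.14 (median 0.64, adjusted p = 2.27e-05; adjusted p = 0.0911 with an estimated correlation). Fetal liver and carcinoma markers rose in 10 of 19 cases and fell in 0 (12 and 1 adjusted over the list alone), with Golm1 up by 3.53 and Anxa2 by 3.71 (median 1.98, adjusted p = 3.77e-08; adjusted p = 0.0693 with an estimated correlation).

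Macrophage markers rose in 10 of 17 cases and fell in 0 (12 and 2 adjusted over the list alone), with Mmp12, the macrophage elastase gene, up by 3.23 and Cd14 by 2.65 (median 0.95, adjusted p = 5.96e-05; adjusted p = 0.26 with an estimated correlation). Of 18 male-biased genes 11 fell and 0 rose (11 and 0 adjusted over the list alone), among them Cyp7b1, an oxysterol hydroxylase gene, by 3.14 and Nudt7 by 2.32 (median -1.56, adjusted p = 2.27e-05; adjusted p = 0.447 with an estimated correlation). Female-biased genes rose in 7 and fell in 3 of 23 cases (10 and 4 adjusted over the list alone), with Cyp3a41a, of the family with shared probe targets, up by 1.77 and Rtn4 by 1.83, at 0.71 to 3.05 over its 3 probes (median 0.47, adjusted p = 0.0265; adjusted p = 0.664 with an estimated correlation and 0.123 with fry). In the sphingolipid pathway 9 of 32 genes rose and 1 fell (13 and 4 adjusted over the list alone), with Sptlc2 up by 1.31, Cerk by 1.06, Degs1, which makes ceramide from dihydroceramide, by 0.93 and Sptlc1 by 0.68, at 0.08 to 0.68 over its 3 probes (median 0.27, adjusted p = 0.0215; adjusted p = 0.26 with an estimated correlation). The stellate cell and fibroblast list was called upward with 1 of 18 genes rising and 0 falling (1 and 0 adjusted over the list alone), which was Timp1 by 3.39 (median 0.55, adjusted p = 0.0265; adjusted p = 0.505 with an estimated correlation and 0.101 with fry). The pancreatic acinar list was called downward with 2 of 10 genes falling, of which Cela1 fell by 0.83 and Try5 fell by 0.72 (0 up and 3 down adjusted over the list alone; median -0.46, adjusted p = 0.033; adjusted p = 0.312 with an estimated correlation). Try5 was not called without WT replicates 1, 2 or 3 (-0.67, -0.55 and -0.74) or Del replicates 1 or 3 (-0.73 and -0.58).

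In all, 4165 genes were called between Del and WT, 2786 higher and 1379 lower in Del, of which 2725 carried a symbol. A fit with the slide by label as a block called 5571 genes. The block by file name and the fit without the 6 samples whose label and file differ each called fewer than the main fit. There were 141 calls within the slide holding 1 Del and 2 WT arrays, and 2550 within the slide holding 3 Del and 2 WT arrays. Between these slides, in that order, the list medians were 2.55 and 2.67 for mitosis, 0.89 and 1.39 for DNA replication, 1.39 and 1.36 for NRF2 targets, 1.34 and 1.95 for fetal liver markers, 0.82 and 0.58 for p53 targets, 0.38 and 1.04 for macrophage markers and -2.02 and -1.42 for male-biased genes. Female-biased genes gave 0.63 (adjusted p = 0.134) and 0.37, sphingolipid genes 0.21 (adjusted p = 0.257) and 0.36, stellate cell genes -0.07 (adjusted p = 0.652) and 0.83, and acinar genes -0.61 and -0.44 (adjusted p = 0.402 in the latter). With the slide as a block these lists, in the same order, had medians of 2.48, 1.29, 1.43, 2.17, 0.69, 0.96, -1.71, 0.63, 0.28, 0.61 and -0.51, and the acinar list missed the threshold (adjusted p = 0.0518). The acinar list was not called without WT replicates 1 or 2 or Del replicate 1 (adjusted p = 0.132, 0.054 and 0.0802). The stellate cell list was not called without WT replicates 2 or 3 or Del replicates 2 or 3 (0.054, 0.113, 0.0688 and 0.0564). The female-biased list was not called without WT replicate 2 or Del replicate 2 (0.0846 and 0.0688). The count was 2189 without Del replicate 3, 7174 without WT replicate 2, and 2768, 2573 and 2662 without WT replicates 1, 3 and 4. Without scaling between arrays 80.5% of 2241 calls were higher in Del, against 66.9% here.

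H/A and Del shared many of their changes against WT, among them those of Atf3, Ly6d and Hsd3b5. Both called 1779 genes higher and 447 lower, where independent lists would share 197.3 and 41, and 0 genes were called in opposite directions. These calls share the WT arrays, which the figure for independent lists leaves out. With H/A against WT and Del against Flox each fitted on its own 8 arrays, so that no array was shared, 1216 genes were called higher in both and 201 lower, where independent lists would share 200.1 and 48.1, and 1 was called in opposite directions. Across genes, which are not independent replicates, the changes correlated with r = 0.841, and the same WT arrays stand in both. With the WT arrays split 2 and 2 between the comparisons r averaged 0.668 (0.559 to 0.741), while simulated unchanged groups set against the same WT arrays gave 0.472 on average and 0.738 at their 95th percentile. The covariance was 0.28, or 0.243 above the simulated mean. H/A against WT set beside Del against Flox, a pairing that was added later and shares no arrays, gave r = 0.734.

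Set directly beside Del, H/A differed in 4 genes, 3 higher and 1 lower in H/A, and 2470 genes had an unadjusted p under 0.05. Kif20b, the gene of a mitotic kinesin, fell by 0.98 in H/A (95% interval -1.28 to -0.67), but its second probe was at -0.26, and the mean of both ended the call of Kif20b in H/A vs Del (-0.62). Snord82 was higher by 1.04 (0.72 to 1.36) and Ccdc24 was higher by 1.77 (1.27 to 2.27), each with adjusted p = 0.0413. Ccdc24 was well above background on 2 of 4 H/A and 1 of 4 Del arrays. The ceramide synthases differed by 0.01 to 0.15, with intervals from -0.39 to 0.69. Camera called 8 lists, of which 0 were called with fry. The strongest were mitosis downward (median -0.45, adjusted p = 2.87e-07) and fatty acid oxidation upward (median 0.15, adjusted p = 0.000123), in which 1 of 45 and 0 of 27 genes were called (1 and 0 adjusted over the list alone) and the adjusted p was 0.594 for both with an estimated correlation. Within the slide holding 3 H/A arrays and 1 Del array the mitosis median was -0.95, and within the other, with 1 H/A array and 3 Del arrays, it was 0.21 (adjusted p = 0.0718), against -0.65 with the slide as a block. For fatty acid oxidation these medians were 0.47, -0.07 (adjusted p = 0.492) and 0.17. The other 6 lists held 0 called genes (1 rising neutrophil gene adjusted over the list alone) and had adjusted p of 0.594 or 0.603 with an estimated correlation. DNA replication (median -0.21, adjusted p = 0.0164) and p53 targets (-0.21, 0.0198) stayed called with the slide as a block. Cholesterol synthesis (0.21, 0.0157), female-biased genes (0.22, 0.0164), fatty acid and triglyceride synthesis (0.19, 0.0198) and neutrophil genes (0.33, 0.0315) did not (adjusted p = 0.122 for the first and 0.156 for the others). Each of the 6 was lost without H/A replicate 3 or without Del replicate 3 (adjusted p from 0.0537 to 0.339). DNA replication, p53 targets and female-biased genes were also lost without H/A replicate 1 (0.0731, 0.182 and 0.0588) or Del replicate 1 (0.075, 0.128 and 0.075), and fatty acid and triglyceride synthesis without H/A replicate 1 (0.0588). With the slide as a block camera called further lists downward. These were NRF2 targets (median -0.28, adjusted p = 0.00603), stellate cell and fibroblast genes (-0.26, 0.00858) and fetal liver markers (-0.17, 0.0275). The 4 calls became 0 with the slide as a block, 75 and 262 within those slides, and 0 without any of H/A replicate 1, WT replicates 1, 3 and 4, Del replicate 4 and Flox replicate 4. They became 1 without H/A replicates 2 or 4, WT replicate 2 or Flox replicate 2, 2 without Del replicates 2 or 3, and 7 without H/A replicate 3. Kif20b stayed called only without Del replicate 1 or Flox replicate 1 (-1.10 to -0.90 over all 16 such fits). Snord82 stayed called only without H/A replicate 3 or Flox replicates 1 or 3 (0.97 to 1.14). Ccdc24 was lost without H/A replicates 1 or 4, WT replicates 1, 3 or 4, Del replicates 2 or 4 or Flox replicate 4 (1.62 to 1.94 over all 16). The 95% intervals allow differences between the lines, and a p above the threshold does not show that they are alike.

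The Flox line was compared with WT to show what that engineered allele does in the liver. Selenbp1 and Selenbp2, genes of selenium-binding proteins, fell in Flox by 2.11 (95% interval -2.59 to -1.62, adjusted p = 0.00119) and 1.91 (-2.32 to -1.51, adjusted p = 0.00066) on the log2 scale, with 4 mice per group. The steroid dehydrogenase genes Hsd3b3 and Hsd3b6 fell by 1.63 and 1.62 (adjusted p = 0.0284 and 0.0366), and Asic5, an ion channel gene, rose by 1.40 (0.98 to 1.83, adjusted p = 0.0227). These were the 5 genes with a symbol among 7 called, 1 higher and 6 lower. Every Flox array lay outside the range of the WT arrays for each of the 5. By gene order in the GRCm38.p6 reference all 5 lie on the chromosome of Cers2, which holds 844 of the 17666 tested genes with a symbol (Fisher's exact test, two-sided, p = 2.46e-07), a comparison chosen after the genes were seen. The test counts the 5 genes as independent. Selenbp1 and Selenbp2 lie near each other and moved alike across arrays, as did Hsd3b3 and Hsd3b6, so this p overstates the evidence. Whether the probes of each pair share targets was not checked. Selenbp1 and Selenbp2 were 15 and 19 tested genes from Cers2, Hsd3b3 and Hsd3b6 73 and 74, and Asic5 210. The 4 that fell also fell in H/A and in Del against WT, whereas Asic5 was not called in either. These falls are all measured against the same WT arrays, so they are not independent of each other. Between Del and Flox, Selenbp1 and Selenbp2 differed by 0.05 and 0.09 and Hsd3b3 and Hsd3b6 by 0.32 and 0.25, and none of these was called.

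Beyond these, 1827 genes had an unadjusted p under 0.05 in Flox against WT. Camera called 5 lists, in which 0 genes were called over all genes and 0 adjusted over the list alone, namely cholesterol synthesis (median -0.24, adjusted p = 0.000122), mitosis (0.30, 0.00121), unfolded protein response (-0.30, 0.00121), fatty acid oxidation (0.16, 0.0128) and stellate cell genes (-0.26, 0.0191), and each had an adjusted p of 0.581 with an estimated correlation. The block fit by slide called 7 genes, and within each slide, with 2 Flox and 2 WT arrays, 0 were. Within those slides, in turn, the medians were 0.02 and -0.55 for cholesterol synthesis, 0.40 and 0.13 for mitosis, -0.50 and -0.04 for the unfolded protein response, 0.20 and 0.03 for fatty acid oxidation and -0.61 and -0.04 for stellate cell genes. With the block they were -0.24, 0.30, -0.30, 0.16 and -0.26. As both groups lay evenly over the slides, the block could not move these medians, so they do not test the slide. The 7 calls became 3 without WT replicate 1 or Flox replicate 3 and 4 without WT replicate 2 or WT replicate 4. Selenbp1 and Selenbp2 stayed called without any 1 of the 16 arrays but not in the fit of the 2 groups alone (-2.11 and -1.91), whereas Asic5 was lost without WT replicates 1, 3 or 4 (1.28, 1.39 and 1.36) or Flox replicates 2, 3 or 4 (1.39, 1.31 and 1.43). Hsd3b3 and Hsd3b6 were lost without any of the WT arrays, Flox replicates 1 or 3, H/A replicate 2 or Del replicates 2 or 3. Hsd3b6 was also lost without H/A replicate 4 or Flox replicate 4. The mean of its 2 probes, at -1.63 and -1.21, ended the call of Hsd3b3 in Flox vs WT (-1.42). Over all 16 such fits Hsd3b3 ranged from -1.75 to -1.47 and Hsd3b6 from -1.76 to -1.45. The list calls were lost without WT replicate 3 or Flox replicate 2 for mitosis (adjusted p = 0.136 and 0.223) and WT replicate 2 for the unfolded protein response (0.108). They were also lost without WT replicate 3 or Flox replicate 1 for fatty acid oxidation (0.0559 and 0.137), and WT replicate 1 or Flox replicate 3 for stellate cell genes (0.266 and 0.157).

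**Figure D3:**
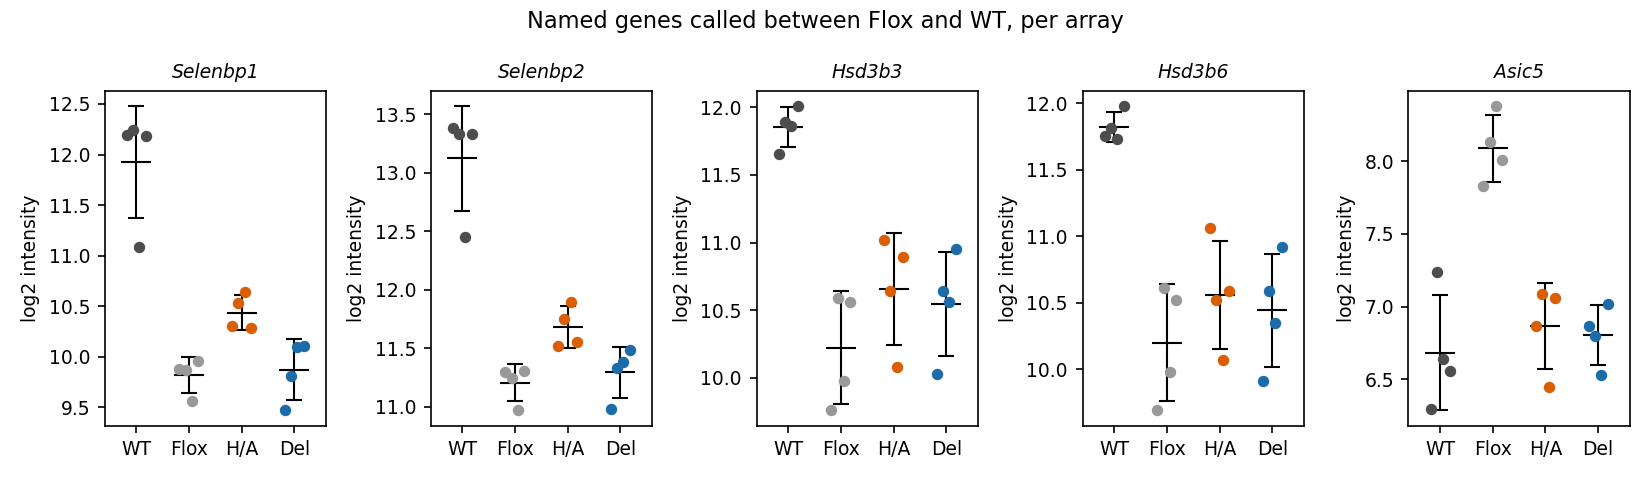
Points are the log2 intensities of single arrays (4 per genotype) for the 5 genes with a symbol called between Flox and WT, and bars are the mean ± SD. Selenbp1, Selenbp2, Hsd3b3 and Hsd3b6 were low in Flox, H/A and Del alike, with WT replicate 3 at 11.09 for Selenbp1, while Asic5 was high in Flox alone.

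Del was also compared with Flox, a difference to which the WT arrays add only their share of the variance estimate. Atf3 was at least 18.5-fold higher in Del than in Flox, Gipc2 at least 29.6-fold and Uhrf1 at least 8.48-fold, and Ly6d rose by 5.01 (95% interval 4.26 to 5.76) and Anxa2, an annexin gene of the fetal liver list, by 4.03. The secreted protease inhibitor gene Slpi rose by 4.53. Snora30 fell by 5.08, Snora28 fell by 3.97, and Snora2b was at least 7.83-fold lower. Hsd3b5 and Serpina4-ps1 fell by 5.08 and 5.41 (adjusted p = 0.00184 and 0.007), with a spread in Flox of 2.76 and 3.30 (SD, n = 4) that came with Flox replicate 1, at 6.09 and 6.71.

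Mitosis genes rose in 32 of 45 cases and fell in 2 (33 and 3 adjusted over the list alone; median 2.10), DNA replication genes in 23 and 2 of 34 (24 and 2; median 1.31), NRF2 targets in 16 and 0 of 20 (16 and 1; median 1.27), fetal liver markers in 14 and 1 of 19 (14 and 1; median 1.73) and p53 targets in 11 and 1 of 21 (12 and 1; median 0.73). Sphingolipid genes rose in 14 and fell in 4 of 32 cases (17 and 7 adjusted over the list alone; median 0.38), with Sptlc2 up by 1.40 and Cerk by 1.33. Stellate cell genes rose in 9 of 18 cases and fell in 0 (12 and 1; median 0.96), with Timp1 at least 7.9-fold higher and Lum and Vim up by 1.70 and 1.00, and macrophage markers in 10 and 3 of 17 (12 and 3; median 0.92). Of 20 genes of the unfolded protein response 4 rose and 1 fell (4 and 1, median 0.53), including Trib3 by 1.23 and Pdia4 by 0.97. Among all 17666 tested genes with a symbol 3634 rose and 3065 fell, so this count of rises is near the share over all genes. In addition, 9 of 18 male-biased genes fell while 0 rose (9 and 0; median -1.61). These 10 lists were called with camera at adjusted p from 4.9e-13 to 0.00514, and with an estimated correlation 0 were, at adjusted p from 0.138 to 0.651.

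In all, 10948 genes were called between Del and Flox, 5231 higher and 5717 lower in Del, of which 6699 carried a symbol. A fit with the slide as a block called 12881. There were 160 calls within the slide holding 1 Del and 2 Flox arrays and 3503 within the slide holding 3 Del and 2 Flox arrays. Between these slides the medians were 1.84 and 2.38 for mitosis, 1.23 and 1.44 for DNA replication, 1.37 and 1.44 for NRF2 targets, 1.44 and 2.00 for fetal liver markers, 0.68 and 0.59 for p53 targets, 0.34 and 0.46 for sphingolipid genes, 0.47 and 1.12 for stellate cell genes and 0.53 and 0.33 for the unfolded protein response. Macrophage markers gave 0.42 (adjusted p = 0.0524) and 1.30, and male-biased genes -1.32 (adjusted p = 0.081) and -1.98. With the slide as a block these lists, in the same order, had medians of 2.14, 1.32, 1.37, 1.71, 0.73, 0.41, 1.02, 0.47, 0.95 and -1.76. The count was 5098 without Del replicate 3 and 6626 without Flox replicate 1, and without scaling between arrays 78% of 4366 calls were higher in Del, against 47.8% here.

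Small nucleolar RNA genes, which guide modification of ribosomal RNA and were grouped only after they appeared among the largest falls, fell in both mutant lines. Of 83 tested, 69 fell and 0 rose in Del against WT at a median of -1.44, 47 fell and 0 rose in H/A against WT at -0.90, and 80 fell and 0 rose in Del against Flox at -1.84. In Flox against WT 0 of 83 were called with limma, at a median of 0.22. With the slide as a block the medians were -1.59, -0.84, -1.88 and 0.22, the last of which could not move, as Flox and WT lay evenly over the slides. Without scaling between arrays the median in H/A against WT was -0.46, with 10 falling and 1 rising, and with the normexp background correction the medians were -0.50 in H/A and -0.58 in Del against WT. The genes that host them in introns had a median of 0.17 in Del against WT, with 0 of 26 called by limma, of 0.22 in H/A against WT, with 1 rising and 2 falling, and of 0.35 in Del against Flox, with 8 rising and 0 falling. Per array, the mean over the small nucleolar RNA genes was -1.84 to -1.66 in Del, and the H/A arrays spread from -1.76 to -0.49.

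**Figure D4:**
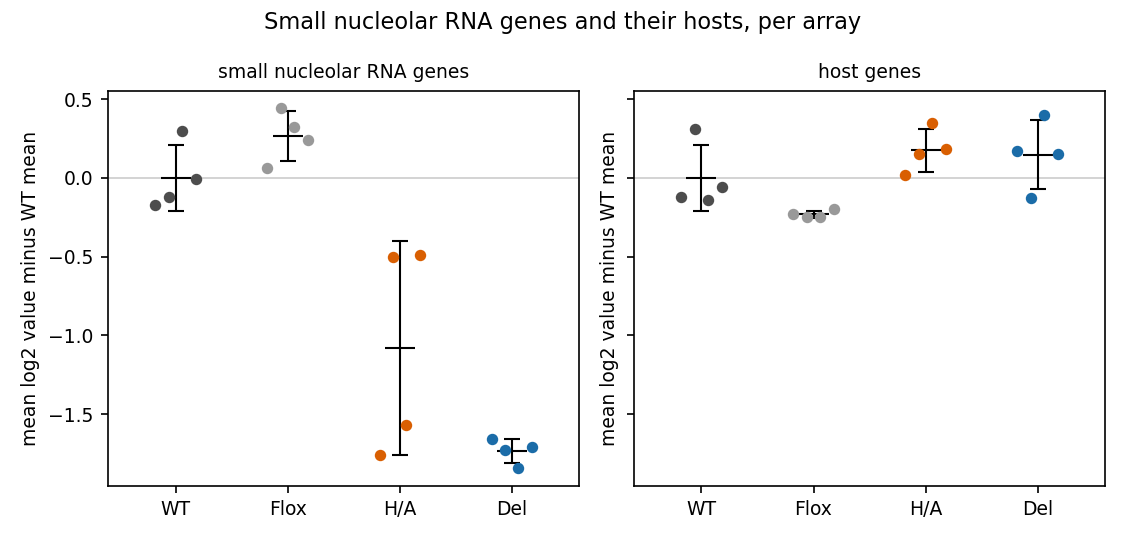
Points are arrays (4 per genotype), bars the mean ± SD, and the vertical axis the mean log2 value over small nucleolar RNA genes (left) or their host genes (right) minus the WT mean. The Del arrays lay between -1.84 and -1.66 and the H/A arrays between -1.76 and -0.49 on the left.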

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

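The tests of the Flox allele's function and of the slide for the genes near Cers2, and that of the slide for the Del counts, were chosen only after the results were seen, as were the lists given splits of their own.

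The gap test took the list scores and the genes that the texts name, a wider first set of genes having been narrowed to these after its values were seen. Within each genotype it picked out 22 of 299 groups of 4 values in which 1 array stood far from the other 3, where chance picks about 1 in 20, or 15. Flox replicate 1 gave 4 of the 22, as did H/A replicate 1. Its scores were -2.29 for male-biased genes (other Flox arrays 0.15 to 0.31) and 1.39 for female-biased genes (-0.19 to 0.05), and its log2 values were 6.09 for Hsd3b5 (11.27 to 11.78) and 6.71 for Serpina4-ps1 (12.93 to 13.84). H/A replicate 1 scored 0.28 for p53 targets (other H/A arrays 0.76 to 0.82) and 0.77 for NRF2 targets (1.60 to 1.75), with 13.36 for Ephx1 and 6.98 for Sptlc2. WT replicate 3 scored -0.52 for male-biased genes (other WT arrays 0.10 to 0.21), with 11.09 for Selenbp1 (12.18 to 12.24) and 12.45 for Selenbp2 (13.33 to 13.38). WT replicate 2 stood at 5.33 for Chaf1a and 7.59 for Abcg1, WT replicate 1 at 0.45 for the pancreatic acinar score and WT replicate 4 at 0.09 for the fatty acid oxidation score. Del replicate 4 scored -1.67 for male-biased genes and H/A replicate 4 scored 0.48 for female-biased genes. Single genes stood apart at 5.07 for Cers5 in Flox replicate 2, 1.83 for Abcb1b in Del replicate 2, 7.47 for S100a8 in Del replicate 1, 11.77 for Igfbp1 in Del replicate 3 and 6.07 for Snord82 in H/A replicate 3.

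The genes with a symbol called between Flox and WT all lay on the chromosome of Cers2. Each slide held 2 Flox and 2 WT arrays by the labels, so the slide as a block could not move their differences, and that 5 of 5 stayed called does not test the slide. With the slide of the file name as a block the calls of Hsd3b3 in Flox vs WT (-1.57), Hsd3b6 in Flox vs WT (-1.56) and Asic5 in Flox vs WT (1.42) were lost. For 6 samples that is not the slide that their column matched, so these losses do not show a slide effect. Sequence from the SV129 strain that stayed linked to the engineered allele may contribute: among the 200 genes with a symbol nearest to Cers2, leaving out the called ones, 24 had an unadjusted p under 0.05, and 0 of 79 other runs of 200 neighbouring genes had as many (highest 20, median 12). A loss of CerS2 function in Flox as large as in Del is argued against as the reason for the falls shared with H/A and Del. Such a loss would put the ratio of the Flox to the Del change near 1 over the shared genes. The 2220 genes called the same way in H/A and Del and not called in Flox had a median ratio of 0 (quartiles -0.17 and 0.16, upper quartile at most 0.21 when 1 array was left out). The Flox changes of the 6 genes called in all 3 were 1.03 to 2.48 times those in Del (1.03 to 1.25 for the 4 with a symbol). These 6 were picked by their call in Flox, which favours large Flox changes, so their ratios are no yardstick for the others. A smaller loss of function cannot be told apart from none, as over all 2226 shared genes the median signed Flox change was 0 (from -0.04 to 0.05 when 1 array was left out), which leaves a small effect possible. These genes were picked as changed against the same WT arrays, which by itself pushes this median above 0. The falls of Selenbp1, Selenbp2, Hsd3b3 and Hsd3b6 were also present in H/A and Del, measured against the same WT arrays. So a difference between strains at these genes could enter those comparisons too. The same 200 genes gave no clear excess there. In H/A against WT 78 had an unadjusted p under 0.05, and 12 of 79 other runs had as many (median 70). In Del against WT 77 did, and 21 of 79 other runs had as many (median 71). With so many genes changed elsewhere, this count could miss a linked difference. No genotypes of the strains were available, and the linked-sequence account stays a hypothesis.

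Small nucleolar RNA genes fell in Del and H/A. A general fall in host transcript levels is argued against by a median host change of 0.17 in Del against WT (quartiles 0.01 and 0.27). The median for the small nucleolar RNA genes was -1.44. The arrays measure transcript levels, and hosts were taken as a set, not matched to single small nucleolar RNA genes. So lower transcription or processing of the hosts of those that fell stays open. In H/A against WT the host median was 0.22, with 1 of 26 rising and 2 falling. A slide difference is argued against too, since their median was -1.59 with the slide as a block. Poorer recovery of all small RNAs cannot be told apart from a change in the cells: other small RNA genes had a median of -0.29, while those that are not microRNA genes had -0.88, with 7 of 18 falling. An effect of the genotype on these RNAs stays open and was not tested otherwise.

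Del differed from Flox in 10948 genes and from WT in 4165, or 38% as many, and the difference between these counts was not itself tested. By the labels, WT and Flox each lay 2 and 2 over the slides, so a constant slide difference would shift both comparisons alike. It cannot by itself set these counts apart. With the slide as a block the counts were 5571 and 12881, or 43.2%, but for that reason the block does not test the slide here. WT replicate 2, which lay nearest to the mutant arrays, cannot be told apart from the other possible reasons: without it the counts were 7174 and 12283, or 58.4%, between the bounds set before the test. A difference between the engineered Flox line and wild type in background stays open and was not tested for these counts.

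Other splits of the 8 arrays of each comparison tested whether a random division gives results as large. For H/A vs WT genes 1 of 35 splits, the real one, gave as many calls (3166, highest other 3089). The same 1 of 35 held for Del vs WT genes (4165, highest other 2667) and Flox vs WT genes (7, highest other 1). It held for Del vs Flox genes too (10948, highest other 2), where no other split came near. Coming first is the smallest share that 35 splits can give, and 5 comparisons were put to it. So it does not by itself exclude chance, and in H/A vs WT another split came close. For H/A vs Del genes 1 of 35 gave as many too (4; 1), but the splits take no account of the slides, over which H/A and Del lie 3 to 1 and 1 to 3. The 4 calls became 0 with the slide as a block, in the fit of the 2 groups alone, and without any of H/A replicate 1, WT replicates 1, 3 and 4, Del replicate 4 and Flox replicate 4. So the splits do not make this count secure. The nearest other split of H/A and WT exchanged H/A replicate 1 with WT replicate 2, and that of Del and WT exchanged Del replicate 2 with WT replicate 2. For the number of gene lists called, chance cannot be excluded: 8 of 35 splits gave as many for H/A vs WT (10; highest other 16), 4 for Del vs WT (11; 13), 21 for Flox vs WT (5; 13), 8 for Del vs Flox (10; 14) and 11 for H/A vs Del (8; 20).

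Single lists were put to the same splits by their camera p. They were picked for their small p in the real split, so coming first among the splits does not exclude chance for them. Over all 32 lists, which share genes and are not independent, the real split gave the smallest p for 5 in H/A vs WT, 5 in Del vs WT and 0 in each of the other 3 comparisons, where a split gives 0.9 on average. In H/A vs WT the real split gave the smallest p, as 1 of 35, for DNA replication (2.73e-15; smallest other 2.37e-11), NRF2 targets (3.15e-13; 1.74e-10), fetal liver and hepatocellular carcinoma markers (7.37e-08; 8.89e-06) and Kupffer cell and macrophage markers (7.39e-08; 4.69e-07). It did not for mitosis, where 2 of 35 splits gave as small a p (7.34e-18; smallest other 1.49e-23), or for male-biased liver genes, where 5 did (5.87e-09; 2.27e-17). In Del vs WT 1 of 35 splits, the real one, gave as small a p for mitosis (4.41e-24; 2.43e-17), DNA replication (1.49e-16; 7.01e-12), NRF2 targets (1.71e-14; 3.69e-10) and fetal liver and hepatocellular carcinoma markers (4.71e-09; 8.62e-08). More splits did so for Kupffer cell and macrophage markers, with 2 (1.3e-05; 1.62e-07), and for male-biased liver genes, with 4 (4.25e-06; 3.79e-10).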

How the results depend on the processing

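The fits of named genes alone, those without small nucleolar RNA genes, and H/A against WT beside Del against Flox were chosen only after the results were seen. No paired analysis was possible because the replicate numbers only follow the order of deposition. Unless a construction is named, the cause of a shift was not tested. The scanner files as listed, in which 6 samples carry another array's signal, gave 5, 0, 0, 0 and 5 genes for H/A vs WT, Del vs WT, Flox vs WT, Del vs Flox and H/A vs Del, 2 and 4 lists for Flox vs WT and H/A vs Del, and 0 ceramide synthase calls. Without those 6 samples the genes were 604, 1258, 3, 245 and 0, with 8 lists in Flox vs WT and 0 ceramide synthase calls. In that fit a single Flox array remained, and the spread came from the other groups. So its gene, list and ceramide synthase counts for Flox vs WT and Del vs Flox say little about Flox. No scaling gave 9543, 2241, 4, 4366 and 34 genes, 10 and 13 lists for Flox vs WT and H/A vs Del, and 3 ceramide synthase calls. It moved the median of all genes in H/A vs Del from -0.01 to 0.40. Normexp gave 10764 genes in H/A vs WT and 1 in H/A vs Del, 19, 9 and 18 lists in H/A vs WT, Flox vs WT and H/A vs Del, and 2 ceramide synthase calls. Array weights gave 13460, 6381 and 9 genes in H/A vs WT, Del vs WT and H/A vs Del, and 2 and 4 lists in Flox vs WT and H/A vs Del.

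The file-name slide as a block gave 2108, 1265, 3 and 0 genes in H/A vs WT, Del vs WT, Flox vs WT and H/A vs Del, and 2 lists in Flox vs WT. This block overlaps with genotype, as it sets all H/A arrays apart from all Del arrays. For 6 samples it is also not the slide that their column matched, so calls lost under it do not show a slide effect. The label slide as a block gave 0 genes in H/A vs Del. Within the file-name slides, with fewer samples, there were 580 genes in H/A vs WT and 0 in Flox vs WT for the first, and 582 in Del vs WT, 0 in Flox vs WT and 4709 in Del vs Flox for the second. Within the label slides there were 14, 141, 0, 160 and 75 genes for the first, with 13 lists in H/A vs Del, and 626, 2550, 0, 3503 and 262 for the second, with 0 lists in H/A vs Del, and 0 ceramide synthase calls in either. Fits of the compared groups alone gave 1826, 2 and 0 genes in H/A vs WT, Flox vs WT and H/A vs Del. A required change of 1 gave 1195, 1590 and 2385 genes in H/A vs WT, Del vs WT and Del vs Flox. The 4 genes of H/A vs Del became 0 with label-paired files or the filter on all 16 arrays, 1 with no filter, an unmoderated model or no small nucleolar RNA genes, and 2 with trend and robust moderation. The unmoderated model gave 3 in Flox vs WT, and named genes alone gave 7098 in Del vs Flox. With an estimated correlation 0 lists were called in every comparison, and fry called 0 in Flox vs WT and H/A vs Del and 16 in Del vs Flox. The correlation of the H/A and Del effects was 0.668 with WT split and 0.734 with no shared arrays.

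Leaving out 1 replicate gave 1450 to 8021 genes in H/A vs WT, 2189 to 7174 in Del vs WT, 3 to 7 in Flox vs WT, 5098 to 12283 in Del vs Flox and 0 to 7 in H/A vs Del. The lists came to 10 to 11, 9 to 13, 3 to 9 (3 without WT replicate 3, 9 without Flox replicate 1), 10 to 13, and 2 to 15 (2 without H/A replicate 3 or Del replicate 3, 5, 15 and 14 without Del replicates 1, 2 and 4), and the ceramide synthase calls to 1 to 10. Of the values of single genes named in the texts, 4232 were the same, 576 weaker, 14 stronger and 4 reversed over the alternatives, and of list values 1399 the same, 176 weaker, 0 stronger and 6 reversed. The next counts leave aside the fits within a slide and those without 1 array, some of which lost more than 4 calls. Single gene values weaker or reversed numbered 16 with the file-name slide as a block, 14 in the 2 groups alone, and 12 with normexp and with no scaling. They numbered 10 with no filter and with an unmoderated model, and 45 without the 6 samples, where a single Flox array remained. The listed files gave 137, and the others 4 or fewer. Reversed values were those of Ccdc24 in H/A vs Del with normexp (-0.03), Cers4 and Cers1 in H/A vs WT without scaling (0.14 and 0.31), and Cers1 in Del vs WT within the first label slide (0.11). Reversed lists, by adjusted p, were those of list mitosis in Flox vs WT without the 6 samples (0.0307) and within the first file-name slide (0.688), and, within the second label slide, fatty acid oxidation in H/A vs WT (0.903) and H/A vs Del (0.492), and mitosis (0.0718) and female-biased genes (0.0812) in H/A vs Del. Both of these mitosis fits of Flox vs WT held a single Flox array, so their p values and reversals say little about Flox. Signal over background limits the dim genes: genes marked on 0 arrays of a group have bounds only.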

Other observations

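The immediate-early test below was chosen only after the result was seen, and the labelling of the growth hormone test was made stricter after its values were seen.

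Several lists that camera did not call as a whole held genes that changed in both mutant lines. Among all 17666 tested genes with a symbol 1604 rose and 515 fell in H/A, and 1938 rose and 787 fell in Del. A list can therefore hold a few called genes without standing out. Fry called lipid uptake upward and bile acid synthesis and transport downward in H/A (adjusted p = 0.00421 and 0.0334) and in Del (0.00533 and 0.00464), and fatty acid and triglyceride synthesis downward in Del (0.00344). In lipid uptake and storage Lpl, the lipoprotein lipase gene, rose by 1.92 in H/A and 2.23 in Del against WT, the nuclear receptor gene Pparg by 1.59 and 1.99 and the fatty acid transporter gene Cd36 by 1.14 and 1.07, though 1 of its 6 probes went the other way at -0.52 and -0.55 (6 of 23 rose and 1 fell in H/A, 6 and 2 in Del; 8 and 1, and 7 and 5, adjusted over the list alone). In fatty acid and triglyceride synthesis Gpat3, which starts glycerolipid synthesis, rose by 2.58 and 2.44 and the desaturase gene Scd2 by 2.17 and 2.30, while Acacb, the gene of an acetyl-CoA carboxylase, fell by 1.60 in H/A and fell by 1.83 in Del, with its second probe at -0.39 and -1.06 (3 of 19 rose and 2 fell in H/A, 2 and 5 in Del; 3 and 5, and 2 and 8, adjusted over the list alone). Abcg1, a cholesterol efflux gene of the lipoprotein list, rose by 1.87 and 1.81 (4 of 21 rose and 1 fell in both; 5 and 1, and 4 and 1, adjusted over the list alone).

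In bile acid handling the phospholipid exporter gene Abcb4 rose by 1.15 in H/A and 1.27 in Del and Slc51b, a subunit of a basolateral bile acid exporter, by 2.58 (0.28 and not called with normexp) and 2.93, while Cyp7b1 fell by 3.16 in H/A and the uptake transporter gene Slc10a1 fell by 1.25 in Del (2 of 20 rose and 3 fell in H/A, 3 and 6 in Del; 3 and 9, and 3 and 7, adjusted over the list alone). Cyp3a11, a drug-metabolising enzyme gene whose probes can share targets, rose by 1.97 and 1.83 in a list that went both ways (5 of 22 rose and 5 fell in H/A, 5 and 6 in Del; 6 and 7, and 6 and 8, adjusted over the list alone). Among acute phase and cytokine genes the chemokine gene Ccl2 rose by 2.00 and 2.01, but was at 0.19 and 0.32 and not called with normexp (5 of 22 rose and 1 fell in H/A, 4 and 0 in Del; 5 and 2, and 5 and 0, adjusted over the list alone). Among neutrophil genes S100a8 rose by 2.15 and 1.70 (3 of 10 rose and 0 fell in H/A, 1 and 0 in Del; 3 and 0, and 1 and 0, adjusted over the list alone). In glucose metabolism Igfbp1 rose by 2.43 and 1.82 (2 of 21 rose and 1 fell in H/A, 1 and 1 in Del; 2 and 1, and 1 and 0, adjusted over the list alone). The counts of rises for glucose genes in both lines were near or below the share over all genes. So were those for bile acid genes in H/A and neutrophil genes in Del. Markers of cholangiocytes (0 of 11 in H/A) and sinusoidal endothelial cells (0 of 15 in H/A and in Del) had few or no called genes.

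The falls of male-biased genes and the rises among female-biased genes gave the hypothesis of lower signalling from growth hormone through STAT5, which maintains the male pattern in mouse liver. Of Socs2, Cish, Igf1 and Igfals, 3 were tested and 0 were called, with medians of -0.62 in H/A and -1.47 in Del against WT. The bound set beforehand, below -0.5 in both, was met, but Flox also had -0.59 and no gene passed on its own, so the data may fit lower signalling without deciding it.

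The rise of Atf3 raised the question whether a general immediate-early response, such as handling of the tissue gives, could account for it. Of 20 immediate-early genes tested, 6 rose in Del against WT, among them Jun by 2.56 and Jund by 1.61, and 0 fell, with a median of 0.54, between the bounds of 0.5 and 1 written for the test. In H/A against WT 9 rose and 0 fell, with a median of 0.56. In Flox against WT 0 rose. The test left the question open.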
